A study of Homo sapiens with 8 samples.

How the data were processed

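RNA was sequenced from Panc1 cells, an established human pancreatic ductal adenocarcinoma line, in 8 libraries of 3 groups. Cells given a control siRNA (siCtrl) were kept at 21% oxygen (normoxia, 2 libraries) or at 1% oxygen (hypoxia, 3 libraries), and cells given an siRNA against SF3B1 (siSF3B1) were kept at 1% oxygen (3 libraries). The labels give 8 hours at 1% oxygen for siSF3B1 cells; their wording leaves open whether this time also holds for siCtrl cells, so the hypoxic groups may differ in time as well. A siSF3B1 group at 21% oxygen was not analysed here, so the effect of the siRNA could not be compared between oxygen levels. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The libraries are named by the numbers in their titles, from 1 to 9, and number 7 was not among those analysed here.

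Libraries were made with a stranded Illumina kit per the labels' protocols, which also mention a ribosomal RNA depletion step. Trimmomatic 0.35, STAR 2.7.0a, SAMtools 1.9, featureCounts, Subread 1.5.0, edgeR 3.24.3 and the genome build GRCh38.p13 are named in the submitters' processing notes, without roles or order. Whether reads were counted by strand is not given in the sources used here, so genes whose exons overlap another measured gene are described as uncertain. The deposited table gives log2 CPM values, that is read counts scaled by library size on a log2 scale, for 15176 genes, 1 value per gene and library, with a prior count that keeps genes without reads on the log scale. The filter that chose these genes is not given in the sources used here. Of the listed genes, 124 had no symbol.

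The deposited log2 values stepped as whole reads do. After the step of each library was found, 100.0% of values came back as whole reads within a tolerance of 0.01 read, with a mean prior count of 2.0 reads. The recovered totals over the listed genes ranged from 20496492 to 25257173 reads. The effective library size that the authors' values imply was 1.055 and 1.044 times the total in the siCtrl normoxia libraries, 1.025, 1.023 and 1.025 times in the siCtrl hypoxia libraries, and 0.949, 0.927 and 0.929 times in the siSF3B1 libraries. The 10 most abundant genes took from 4.36 to 5.58% of the reads of a library. In the shallowest library 3 reads correspond to 0.158 CPM, and 595 genes had under 3 reads in at least 1 library. Within groups, pairs of libraries differed by more than sampling noise, with a chi-square per degree of freedom from 8.65 to 21.4, so none was counted as a repeat of another.

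Genes with a mean log2 CPM above 0 over all 8 libraries, that is above 1 CPM, were tested, which kept 13112 genes and left out 2064. The log2 values were used as deposited, with no further pseudocount. A linear model with 1 mean per group was fitted to all 8 libraries, leaving 5 residual degrees of freedom, with limma 3.58.1 in R 4.3.3 and an intensity trend in the prior variance. Tests were two-sided, p-values were adjusted with the Benjamini-Hochberg method over the genes tested, and genes with an adjusted p under 0.05 are called changed. The table holds log2 values and not counts, so edgeR was not used for the tests; limma's voom on the recovered reads was run as an alternative. Fold changes of genes near the floor are drawn toward 0 by the prior count.

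Before the data were examined, 26 gene lists were fixed, and the 23 with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. None of the mitochondrially encoded mRNAs of 1 list was analysed here, and the fibroblast list and the list of blood and endothelial cell markers had under 5 tested members. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction, were alternatives. The estimated correlation rests on 5 residual degrees of freedom and its power was not tested. A list that it leaves uncalled is therefore not shown to be unchanged. The rule for named genes was also fixed before the data were examined. It takes SF3B1, HIF1A, EPAS1 and ARNT; per comparison the 10 called genes with the highest and the 10 with the lowest log2 fold change that have a symbol, a mean log2 CPM of at least 1 and no overlap between the libraries of both groups; up to 4 called members per list with the smallest p, or where none was called up to 2 with the largest fold change; the 10 genes called in opposite directions by hypoxia and by SF3B1 siRNA with the largest smaller fold change; and the 5 such genes called in the same direction. Many of the genes that this rule takes have no result in the text. The gene families in the closing section were chosen after the data were seen.

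Library numbers in the titles fall into the sets 1 to 3, 4 to 6 and 7 to 9, each with at most 1 library per group. The labels do not say what the numbers mark. Deviations from the group means correlated between libraries of the same set, with r from 0.34 to 0.43 in 7 pairs, and between sets with r from -0.42 to 0.06 in 14 pairs. The latter lean negative by construction, because deviations sum to 0 within a group and those of the 2 siCtrl normoxia libraries mirror each other; these correlations are across genes, which are not independent replicates. The sets were therefore treated as a likely pairing of the libraries. The main fit, fixed beforehand, has no block, so printed SEs, intervals, p-values and counts leave this pairing out unless the block is named. The fit with the set as a block is given beside a printed result where it changes the call of a gene or list. It is also given where it moves a count of calls by over 1.5 times, while smaller shifts of a list's counts are not given.

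The other alternatives were fits without the trend and with a robust prior, no filter and a stricter filter at a mean log2 CPM of 2, median-centred and quantile-normalized libraries, pseudocounts of 1 and 5 CPM, fits on only the 2 groups compared, array quality weights, each library left out in turn, and for counts of genes an adjusted p under 0.01 or a log2 fold change of at least 1 in size. Where a library left out leaves a group with 1 library, that library is assumed to vary like the other groups. Leaving out a library of a compared group also lowers the power of the test, most of all there. A call lost in this way does not show that 1 library carried the change. Scaling by plain read totals, and the estimated correlation together with the block, were added after the data were seen.

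The hypoxia and the knockdown comparison share the 3 siCtrl hypoxia libraries with opposite sign. Groups without effects were simulated 100 times, once with the gene-gene correlation of the residuals kept and once with independent genes. A first version that permuted residuals among libraries was replaced after its result had been seen, because residuals sum to 0 within a group and permuted residuals are therefore not independent draws. That version gave a mean covariance of -0.0186 (range -0.0537 to 0.0131) and up to 175 genes called in opposite directions. Simulations with the library-number sets, drawn from the estimated set effects and the residuals of the blocked fit, and splits of the siCtrl hypoxia libraries between the comparisons were added after the data were seen. A comparison left with 1 siCtrl hypoxia library assumes that it varies like the others.

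The tests were tried on simulated reads with 200 changed genes, drawn with an assumed dispersion of 0.01. For the hypoxia design 39.4% of genes changed by 0.5 log2 units, 97% of those changed by 1 and 100% of those changed by 2 were called, over 13214 genes, and 3.1% of calls were false. For the knockdown design the shares were 71.6%, 100% and 100% over 13212 genes, with 4.3% false calls. In the knockdown design camera called the 1 list that was shifted. The simulated reads carry no correlation between genes, so false list calls were not tested. They also hold 1 dispersion for all genes and no effects of the library-number sets. Far more than 200 genes were called in the real knockdown comparison. The shares of true and false calls therefore hold for the simulated setting only.

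Gene positions, exon numbers and overlaps were taken from GENCODE release 29 on GRCh38, in which 14813 of the 15176 genes (97.6%) were matched. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.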

Results

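Gene expression was measured by RNA sequencing in Panc1 pancreatic cancer cells treated with control siRNA at 21% oxygen (n = 2 libraries), control siRNA at 1% oxygen (n = 3) or SF3B1 siRNA at 1% oxygen (n = 3). SF3B1 is a core subunit of the U2 small nuclear ribonucleoprotein, which recognises the branch point during splicing. HIF1A encodes the oxygen-regulated subunit of the transcription factor HIF-1. The recovered depth over the listed genes was 22364467 and 25257173 reads in the siCtrl normoxia libraries, 22502783, 21310040 and 23352189 reads in the siCtrl hypoxia libraries and 22123927, 22861680 and 20496492 reads in the siSF3B1 libraries.

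The targeted gene was examined first. SF3B1 (Entrez gene 23451, chromosome 2, 197389784 to 197435091 on the minus strand of GRCh38, up to 25 exons) stood at 8.88 ± 0.013 log2 CPM (SD, n = 2) in siCtrl normoxia, 8.77 ± 0.084 (SD, n = 3) in siCtrl hypoxia and 5.35 ± 0.14 (SD, n = 3) in siSF3B1 hypoxia. SF3B1 siRNA lowered it by 10.7-fold in hypoxia, a log2 fold change of -3.43 (95% CI -3.60 to -3.25, limma adjusted p = 9.69e-09), and all 3 siSF3B1 libraries lay below all 5 siCtrl libraries. The lowest siSF3B1 library still held 768 SF3B1 reads. Hypoxia alone gave a log2 fold change of -0.10 for SF3B1 (SE 0.087, adjusted p = 0.554).

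HIF1A (Entrez gene 3091, chromosome 14, 61695513 to 61748259 on the plus strand) was lower in hypoxia and higher again with SF3B1 siRNA. Its level was 6.90 ± 0.017 log2 CPM (SD, n = 2) in siCtrl normoxia, 5.26 ± 0.314 (SD, n = 3) in siCtrl hypoxia and 6.15 ± 0.214 (SD, n = 3) in siSF3B1 hypoxia. The hypoxia change was -1.65 on the log2 scale (SE 0.167, limma adjusted p = 0.000222), and the change with SF3B1 siRNA was 0.89 (SE 0.149, adjusted p = 0.000429). EPAS1, which encodes HIF-2alpha, did not pass the test in hypoxia (log2 fold change -0.15, adjusted p = 0.248) and was higher by 0.43 (SE 0.059, adjusted p = 0.000105) with SF3B1 siRNA. ARNT, the partner subunit of both, gave 0.002 in hypoxia (SE 0.081, adjusted p = 0.993) and fell by 0.92 with SF3B1 siRNA (SE 0.072, adjusted p = 2.69e-06). These values are for mRNA, and protein was not measured in the data used here.

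**Figure D1:**
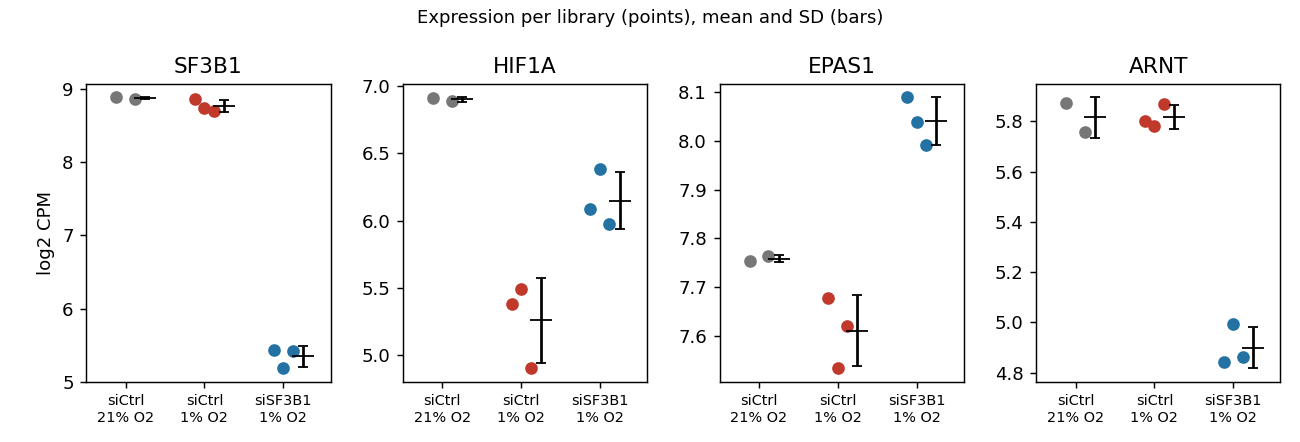
Expression of SF3B1, HIF1A, EPAS1 and ARNT in log2 CPM (y axis, a different range in each panel) per library (points) in the 3 groups (x axis), with group means and SD as bars. The 3 siSF3B1 libraries lie below the other 5 for SF3B1 and for ARNT.

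The first comparison asked what 1% oxygen changed in siCtrl cells. Genes that HIF activates rose together. Of 32 tested members of a list of canonical HIF targets outside glycolysis, 32 rose and 0 fell, with a median log2 fold change of 1.99. PPFIA4, a liprin family member, rose by 5.33 (SE 0.198, limma adjusted p = 1.96e-07), ANGPTL4, a secreted regulator of lipoprotein lipase, by 3.62 (SE 0.086), BNIP3, a mitophagy receptor, by 2.58 (SE 0.08) and AK4, a mitochondrial adenylate kinase, by 2.05 (SE 0.074); ANGPTL4 overlaps an antisense gene and is uncertain to that extent. Of 21 tested genes of glycolysis and lactate export, 20 rose and 0 fell, with a median of 1.29. Among them were SLC2A1, the glucose transporter GLUT1 (2.73, SE 0.089), PDK1, a kinase that inhibits pyruvate dehydrogenase (2.83, SE 0.097), ENO2, an enolase (2.74, SE 0.155), and PFKFB4, which sets fructose 2,6-bisphosphate levels (4.57, SE 0.217); SLC2A1 overlaps an antisense gene, and PFKFB4 shares exon sequence with UCN2, so both values are uncertain.

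Of 11 tested components of the HIF pathway 3 rose, 1 fell and 7 were not called, with a median of 0.002 (-0.03 with plain read totals). Camera did not call the list (adjusted p = 0.179), while fry called it higher (adjusted p = 0.00168). EGLN1 and EGLN3, prolyl hydroxylases that mark HIF subunits for degradation and also members of the list of canonical targets, rose by 1.58 (SE 0.085) and 2.06 (SE 0.157), and CITED2, which competes with HIF for p300, by 1.76 (SE 0.1), while HIF1A was the member that fell. Adjusted over the list alone, these counts were the same. Other genes with high fold changes were DEPP1, which overlaps RASSF4 on the other strand (3.72, SE 0.086), IGFBP3, which binds insulin-like growth factors (10.5-fold, adjusted p = 9.9e-05), and PPP1R3C, a glycogen-targeting subunit of protein phosphatase 1 (3.41, SE 0.188). Among the genes with the lowest fold changes were HIF1A and EREG, the growth factor epiregulin (-1.53, SE 0.17). The other 8 of the 10 named there each lost the call when 1 library was left out, among them TXNIP, an inhibitor of thioredoxin and glucose uptake (-1.65, SE 0.337, adjusted p = 0.0185; 0.218 without siCtrl_Nx replicate 4, 0.0693 without siCtrl_Hx replicate 2 and 0.0716 without siCtrl_Hx replicate 8).

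Without the library-number sets as a block, a minority of the members of other lists were called in hypoxia, against 5.7% of all tested genes. The called share was above this in the EMT, immediate early, intronless and stress response lists and below it in the others. VLDLR, a lipoprotein receptor in the list of the integrated stress response and unfolded protein response, rose by 2.68 (SE 0.266), and DUSP1, a MAP kinase phosphatase among the immediate early genes, by 1.11 (SE 0.109). In each of these lists 3 members rose and 0 fell, of 28 and 18 tested; with the block 10 stress response genes rose, and 5 immediate early genes rose and 2 fell. The other members called were EDEM1 and SLC7A5 in the stress response list and JUN and MYC among the immediate early genes. Each lost the call without siCtrl_Nx replicate 4 and without other libraries. Without siCtrl_Nx replicate 4 their log2 fold changes were 0.441, 0.437, 0.707 and 0.258, against 0.464, 0.478, 0.741 and 0.36 with all 8 libraries. Of 29 EMT and matrix genes 3 rose and 2 fell, of 24 intronless genes 3 rose and 0 fell, and of 23 p53 targets 1 fell. With the block 7 EMT genes rose and 3 fell, 6 intronless genes rose, and 2 p53 targets rose and 3 fell. Of the genes called without it, THBS1, TGFBI, TGFBR1, KCTD12, FOXC2 and PLK3 each lost the call without siCtrl_Nx replicate 1 (adjusted p = 0.0699, 0.101, 0.0818, 0.161, 0.182 and 0.128); THBS1, FOXC2 and PLK3 overlap FSIP1, FOXC2-AS1 and TCTEX1D4 on the other strand and are uncertain. LOXL2, the called EMT gene with the smallest p, kept its call under every alternative. Adjusted over the list alone, 4 rose and 2 fell among EMT genes, 7 rose among intronless genes, 5 rose and 2 fell among immediate early genes, and 1 rose and 3 fell among SR and hnRNP factors. Without the block no member was called among 28 DNA replication genes, 28 mitosis genes, 35 genes of the TCA cycle and respiratory chain, 25 ribosome biogenesis genes, 32 cytosolic ribosomal proteins, 23 cholesterol genes, 23 interferon-stimulated genes, 13 heat shock proteins, 24 genes of autophagy and lysosome, 12 NF-kB genes, 19 apoptosis regulators, 11 ductal markers or 7 histone genes. With it 1 DNA replication gene rose and 2 fell, 2 mitosis genes fell, 1 gene of the TCA list and 1 of ribosome biogenesis fell, 3 cholesterol genes rose, and 1 heat shock protein rose and 1 fell. It also called 2 autophagy genes higher and 2 lower, 2 NF-kB genes higher and 1 lower, 2 apoptosis regulators higher and 1 lower, and 4 ductal markers higher. Quantile normalization called 1 mitosis gene, 2 ribosome biogenesis genes, 1 heat shock protein and 1 apoptosis regulator lower, and plain read totals 1 mitosis gene, 1 ribosome biogenesis gene and 1 autophagy gene.

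In total 741 of 13112 tested genes were called in hypoxia (limma, adjusted p under 0.05), 570 higher and 171 lower, and 212 of them changed by a log2 fold change of at least 1 in size. With the library-number sets as a block the count was 1645, with 1048 higher and 597 lower. The count depended on the libraries kept: it was 418 without siCtrl_Hx replicate 2 and 411 without siCtrl_Hx replicate 8. It was lower still with either siCtrl_Nx library left out, where 1 normoxia library remains and power is lower by design. With libraries scaled by plain read totals 505 were higher and 275 lower. Camera called 8 of 23 lists, 3 up (HIF targets, adjusted p = 2.52e-58; glycolysis, 8.72e-35; stress response, 0.00042) and 5 down. With an estimated correlation none was called (adjusted p = 0.0649 for HIF targets, 0.066 for glycolysis, 0.728 for the stress response), and fry called 4. The lists with a lower camera direction were ribosome biogenesis, mitosis, U2 proteins, SR and hnRNP factors and DNA replication, in which 1 member fell and 1 rose over all 5 (adjusted p = 0.645, 0.728, 0.482, 0.719 and 0.728 with an estimated correlation). With the block 1, 2, 4, 5 and 2 members fell in these lists, and 1 SR and hnRNP factor and 1 replication gene rose; with quantile normalization or plain read totals 3 SR and hnRNP factors fell. The 2 members called without the block, SF3B4 (-0.35) and CLK3 (0.49, uncertain since it overlaps EDC3 on the other strand), each lost the call without siCtrl_Nx replicate 1 (0.145 and 0.141) and without other libraries. The list call for SR and hnRNP factors was lost under the block (adjusted p = 0.064), without siCtrl_Nx replicate 1 (0.117) and without siCtrl_Hx replicate 8 (0.115), that for DNA replication without siCtrl_Hx replicate 2 (0.188) or siCtrl_Nx replicate 4 (0.453), and that for mitosis without siCtrl_Hx replicate 8 (0.0788).

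The second comparison asked what SF3B1 siRNA changed at 1% oxygen. The labels give 8 hours at this level for siSF3B1 cells and leave open whether siCtrl cells had the same time. The genes of DNA replication were lower: 27 of 28 tested members fell and 0 rose, with a median log2 fold change of -1.45. CDC45, a subunit of the replicative helicase, fell by 3.06 on the log2 scale (SE 0.122, limma adjusted p = 9.27e-08), CDC6, a licensing factor, by 2.90 (SE 0.128), and E2F1, a transcription factor of S phase genes, by 2.28 (SE 0.083). Of 28 mitosis genes 15 fell and 5 rose (17 and 5 adjusted over the list alone, 18 and 2 with plain read totals, 11 and 5 with median-centred libraries), with a median of -0.29; TOP2A fell by 1.42 (SE 0.134), the kinesin KIF11 by 1.42 (SE 0.135) and CDK1 by 1.09 (SE 0.131). SKP2, the ubiquitin ligase subunit that targets p27, fell by 3.01 (SE 0.115). The replication list was called by camera (adjusted p = 1.06e-12) and by fry (0.000318), not with an estimated correlation (adjusted p = 0.612). The mitosis call (camera adjusted p = 0.0477) was lost without siCtrl_Hx replicate 5 (0.133), siCtrl_Hx replicate 2 (0.0658), siSF3B1_Hx replicate 3 (0.149) or siSF3B1_Hx replicate 9 (0.0597), with plain read totals (0.0519), and with an estimated correlation (adjusted p = 0.783). Fry did not call the mitosis list (adjusted p = 0.168). Another split of the 6 hypoxic libraries into 3 and 3, which mixed the siRNAs, gave this list a larger median in size (0.415).

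HIF targets were lower with SF3B1 siRNA. Of 32 tested canonical targets 24 fell and 0 rose (25 and 2 with the block), with a median of -0.68. BNIP3 fell by 1.76 (SE 0.071, adjusted p = 9.71e-08), PPFIA4 by 1.68 (SE 0.177), KDM4B, a histone demethylase, by 1.46 (SE 0.155) and AK4 by 0.90 (SE 0.067). In the glycolysis list 12 fell and 2 rose of 21, with a median of -0.27. GPI, glucose-6-phosphate isomerase, fell by 1.55 (SE 0.122), PFKFB4 by 1.45 (SE 0.194), ENO2 by 1.26 (SE 0.139) and PDK1 by 1.12 (SE 0.087). Both glycolysis genes that rose, ENO1 and PKM, were not called higher with quantile normalization or plain read totals, where 0 rose and 16 or 15 fell. Adjusted over the list alone, the counts of both lists and of DNA replication were the same. Both lists were called by camera (adjusted p = 5.41e-05 and 0.0204) and fry (0.00275 and 0.0105), and not with an estimated correlation (adjusted p = 0.612 and 0.627). Camera also called HIF targets in 6 and glycolysis in 5 of 9 splits of the hypoxic libraries that mixed the siRNAs. Their medians there reached 0.405 and 0.247 in size. These splits keep part of the siRNA difference, but the camera call alone does not mark the real grouping.

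**Figure D2:**
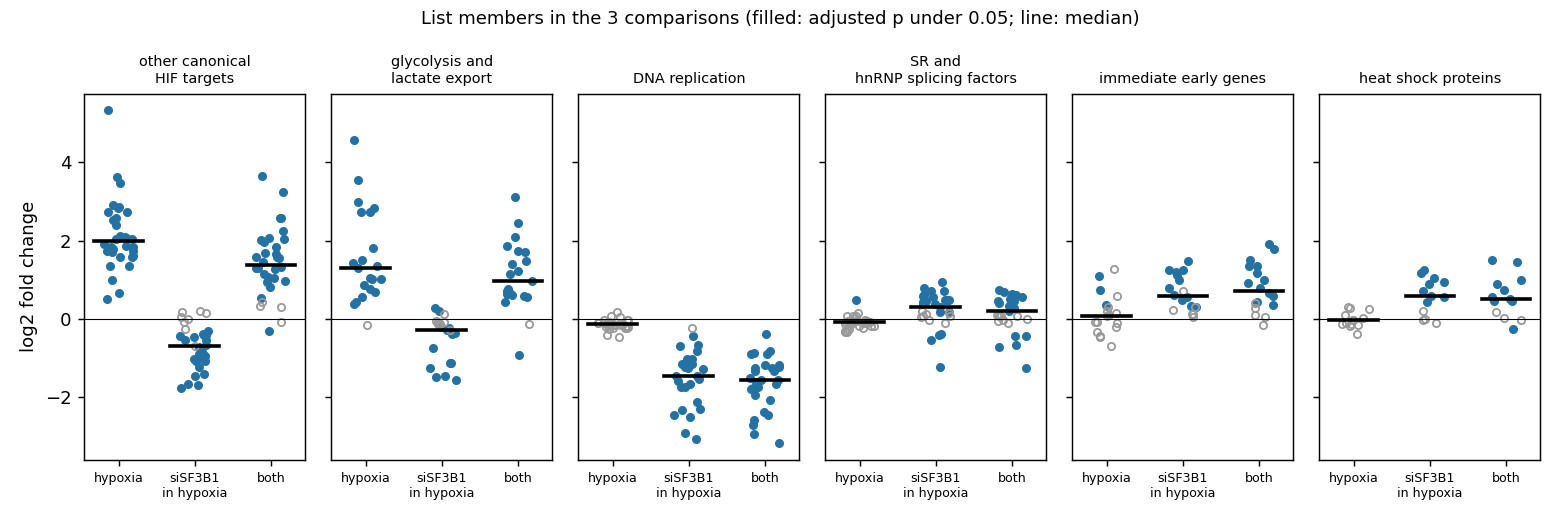
Log2 fold changes (y axis) of the tested members of 6 lists in hypoxia, with SF3B1 siRNA in hypoxia, and in siSF3B1 hypoxia against siCtrl normoxia (x axis, marked both). Filled points have an adjusted p under 0.05 and lines are medians; the median of the HIF target list is 1.99, -0.68 and 1.39, and that of DNA replication is -0.14, -1.45 and -1.56.

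Heat shock, immediate early, interferon-stimulated, and autophagy and lysosome genes were higher with SF3B1 siRNA, while the stress response, p53 and NF-kB lists were not called by camera (adjusted p = 0.142, 0.142 and 0.307). With the library-number sets as a block the stress response list was called (camera adjusted p = 0.0495). Of 13 heat shock proteins 9 rose and 0 fell (2 fell with quantile normalization, 1 with plain read totals), with a median of 0.59; BAG3, a co-chaperone, rose by 0.89 (SE 0.066) and DNAJB1 by 1.04 (SE 0.087, overlapping TECR on the other strand), while HSPA1A (1.18) and HSPA1B (1.25) are near-identical copies and their separate values are uncertain. Of 18 immediate early genes 12 rose and 0 fell, with a median of 0.59, among them DUSP6 (1.11, SE 0.107), KLF4 (1.47, SE 0.195), DUSP1 (0.80, SE 0.097) and DUSP2 (1.25, SE 0.191). Of 23 interferon-stimulated genes 13 rose and 2 fell, with OASL at 2.27 (SE 0.153), IFI6 at 1.65 (SE 0.112) and ISG15 at 1.22 (SE 0.115); the median was 0.597, and a split of the 6 hypoxic libraries that mixed the siRNAs gave 0.684 in size. Of 24 genes of autophagy and lysosome 16 rose and 4 fell, including the lysosomal membrane proteins LAMP2 (1.04, SE 0.062) and LAMP1 (0.58, SE 0.052). Camera adjusted p-values of these 4 lists were 0.0103, 0.0103, 0.0235 and 0.0204; with an estimated correlation the adjusted p was 0.612, 0.612, 0.627 and 0.612. The heat shock call was lost with quantile normalization (adjusted p = 0.0517), and the interferon call with the stricter filter (0.0648). Adjusted over the list alone, the counts of these 4 lists were the same. Camera also called them in 6, 5, 4 and 3 of 9 splits of the hypoxic libraries that mixed the siRNAs.

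Splicing factors moved in both directions. Of 29 SR and hnRNP factors and CLK kinases 17 rose and 4 fell, with HNRNPL at 0.93 (SE 0.064), HNRNPR at 0.70 (SE 0.057) and SRSF8 at 0.79 (SE 0.065) against HNRNPU at -1.21 (SE 0.066, overlapping COX20 on the other strand). The list was called by camera (adjusted p = 0.0204; 0.135 with quantile normalization; adjusted p = 0.612 with an estimated correlation). Of 20 U2 and SF3B-SF3A proteins 11 rose and 6 fell (11 and 7 adjusted over the list alone), and the list was not called (adjusted p = 0.307); SNRPB2 rose by 1.05 (SE 0.062), SNRPA1 fell by 1.19 (SE 0.07) and DDX42 by 1.21 (SE 0.054, overlapping CCDC47 on the other strand). SF3B1 itself is among the 6. Of 32 cytosolic ribosomal proteins 19 rose and 4 fell, or 19 and 5 adjusted over the list alone (camera adjusted p = 0.0291; adjusted p = 0.627 with an estimated correlation), but with quantile normalization 7 rose and 6 fell and the camera direction turned (0.773), with plain read totals the adjusted p was 0.121, and without siSF3B1_Hx replicate 9 it was 0.0528.

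Among single genes, the highest fold changes with SF3B1 siRNA included GUCA1B, a guanylate cyclase activator (5.04, SE 0.22), MYLK2, a myosin light chain kinase (5.03, SE 0.419), DDR2, a collagen receptor (3.72, SE 0.181), and SAT1, the polyamine acetyltransferase (2.71, SE 0.1). The lowest after SF3B1 and CDC45 were PHF7 (-3.03, SE 0.136), PRX (-3.02, SE 0.191) and SKP2. Of markers of other cell types THY1 was higher by 1.37 (SE 0.095) among 4 tested fibroblast genes, and CD14 by 1.16 (SE 0.261) and CD68 by 0.44 (SE 0.158) were both tested blood cell markers; the CD68 call was lost under several alternatives, for example without siCtrl_Hx replicate 2 (adjusted p = 0.119), siCtrl_Hx replicate 8 (0.0602), siSF3B1_Hx replicate 6 (0.104) or siSF3B1_Hx replicate 9 (0.0657).

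In total 8650 of 13112 genes (66%) were called with SF3B1 siRNA, 4595 higher and 4055 lower; 1842 changed by at least 1 log2 unit, of which 705 were higher and 1137 lower. With libraries scaled by plain read totals 3551 were higher and 4956 lower, and the median log2 fold change of all tested genes was -0.10 instead of 0.03, so directions of small changes are relative to the scaling. Camera called 10 of 23 lists, fry 17 and camera with an estimated correlation 0.

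The third comparison set siSF3B1 hypoxia against siCtrl normoxia, where siRNA and oxygen both differ. Canonical HIF targets were still higher: 27 rose and 1 fell of 32, with a median of 1.39, and 19 of 21 glycolysis genes rose and 1 fell, with a median of 0.98. ANGPTL4 was 9.45-fold higher (adjusted p = 2.29e-08), SLC2A1 by 2.46 (SE 0.089), PDK1 by 1.72 (SE 0.097) and ERO1A, an endoplasmic reticulum oxidase, by 1.59 (SE 0.094). All 28 DNA replication genes fell, with a median of -1.56. PGF, placental growth factor, was higher by 3.74 (SE 0.211). Of 28 stress response genes 20 rose and 2 fell, with a median of 0.67. In total 8178 genes were called, 4473 higher and 3705 lower (3173 and 4828 with plain read totals). Camera called 11 of 23 lists, with none at an estimated correlation (lowest adjusted p = 0.491).

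Genes that hypoxia changed were then followed with SF3B1 siRNA. Of the 570 genes that rose in hypoxia 280 fell with SF3B1 siRNA and 98 rose, and of the 171 that fell in hypoxia 120 rose with SF3B1 siRNA and 27 fell. Independent lists of these sizes would share 176.3, 199.8, 59.93 and 52.88 genes. FGF11, an intracellular FGF family member, rose by 2.92 (SE 0.296) in hypoxia and fell by 2.45 (SE 0.264) with SF3B1 siRNA, BNIP3 went from 2.58 to -1.76, ZNF395, a zinc finger gene, from 2.26 (SE 0.148) to -1.74 (SE 0.132), and HILPDA, a lipid droplet protein, from 2.72 (SE 0.254) to -1.65 (SE 0.228). TXNIP fell and PGF and TRIM46 rose in both comparisons; TRIM46 gave 1.01 (SE 0.15) and 1.72 (SE 0.134).

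Both comparisons use the siCtrl hypoxia libraries with opposite sign, so part of the excess of opposite changes may come from these shared controls. The covariance of both log2 fold changes over all tested genes was -0.0489. Simulated groups without effects gave a mean of -0.013 (range -0.0649 to 0.0295 over 100 draws) with the gene-gene correlation kept and -0.0133 (range -0.015 to -0.0117) with independent genes. In either, 0 genes were called in opposite directions. Groups without effects give few calls at all, so the simulated counts cannot be used to judge the observed count of 400. With the library-number sets in the simulation the mean was -0.00765 (range -0.0471 to 0.0237) without the block. With the block the observed covariance was -0.0521 and the simulated mean -0.00752 (range -0.0499 to 0.0291), with up to 44 genes called in opposite directions. The 3 siCtrl hypoxia libraries were also split between the comparisons, 1 or 2 for hypoxia and the others for SF3B1 siRNA, in 6 ways. The covariance was then from -0.0494 to -0.0227, below the simulated range in 2 of the 6, and from 122 to 231 genes were called in opposite directions by limma, where independent lists of these sizes would share from 54.32 to 145.3. The count of 400 opposite genes was 881 with the block, and 162, 181, 214 and 214 without siCtrl_Nx replicate 1, siCtrl_Nx replicate 4, siCtrl_Hx replicate 2 and siCtrl_Hx replicate 8.

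**Figure D3:**
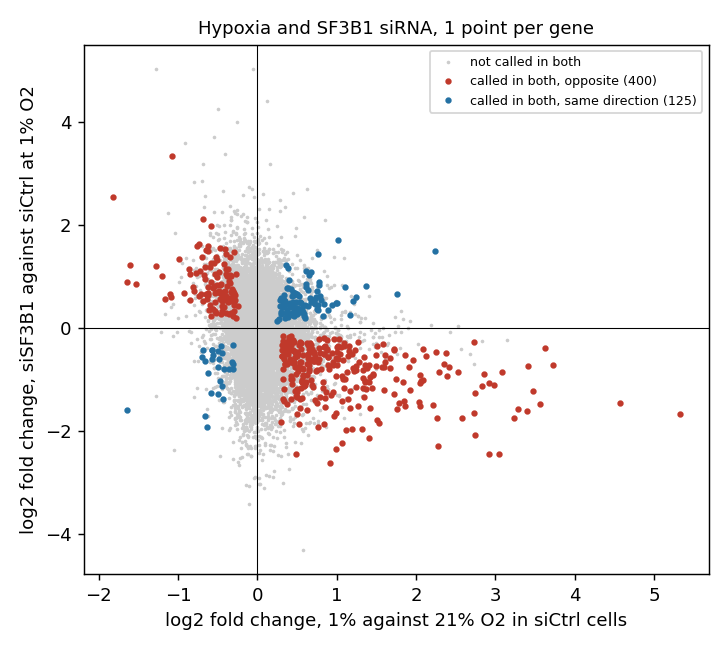
Log2 fold change in hypoxia (x axis) against that with SF3B1 siRNA in hypoxia (y axis), 1 point per tested gene. The 400 genes called in both comparisons in opposite directions and the 125 called in the same direction are coloured.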

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

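Scaling by plain read totals and the estimated correlation with the block were chosen after seeing the data. The fall of SF3B1 kept its direction and call under every alternative, from -3.27 with a pseudocount of 5 CPM to -3.56 with plain read totals. The number of genes changed by hypoxia was 741; it was 1274 with array quality weights, 1645 with the library-number set block, 336 at an adjusted p under 0.01, 212 with a log2 fold change of at least 1, and from 278 to 881 with each library left out. For opposite changes the 400 genes became 654 with array quality weights, 881 with the block, and from 162 to 467 with each library left out. In the knockdown and siSF3B1 hypoxia against siCtrl normoxia comparisons the count left the range of 1.5 times only with the added fold change threshold, 1842 and 1893. Stricter thresholds lower counts by construction, and a library left out of a compared group lowers the power of the test. For the rest the cause was not tested. The block added calls for 16 named genes in hypoxia and removed none; it removed the hypoxia call of SR and hnRNP factors and added calls for ductal markers in hypoxia and in the third comparison, stress response (0.0495) and EMT genes (0.0291) with SF3B1 siRNA, and intronless genes in the third comparison. It changed no other list call by camera at the preset correlation, and no other single gene in the comparison that named it; elsewhere it added calls, such as VLDLR with SF3B1 siRNA (0.0867 to 0.0321) and DUSP2 in hypoxia (0.108 to 0.0055).

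With an estimated correlation 0 lists were called in each comparison, with and without the block. Even HIF targets in hypoxia, where 32 of 32 rose, were left uncalled (camera adjusted p = 0.0649, estimated correlation 0.35). So was DNA replication with SF3B1 siRNA, where 27 of 28 fell (camera adjusted p = 0.612, estimated correlation 0.538). The lack of a call in this version therefore says little about a list. Fry called 4 in hypoxia, 17 with SF3B1 siRNA and 19 in the third comparison, against 8, 10 and 11 by camera. Directions turned for ribosomal proteins with quantile normalization (adjusted p = 0.773 with SF3B1 siRNA and 0.726 in the third comparison), for cholesterol genes in hypoxia without siCtrl_Nx replicate 4 (0.0184; from 0.000527 to 0.618 with each library left out) and for U2 proteins in the third comparison with fry (0.0128); the cause was not tested. Of 318 results for single named genes, 276 kept their side of the threshold under every alternative, with the same direction where called. Under some alternative 42 lost or gained a call, and 0 called results reversed. A change of sign was not counted for a gene that was called in neither fit. Of 69 list results 43 kept their call or lack of one under every alternative that kept the preset correlation, and 13 under all alternatives. In 12 and 29 a call was lost under some. A turn of direction was not counted for a list called in neither test. Depth limits the lowest genes, since 595 of the listed genes had under 3 reads in at least 1 library.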

Other observations

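The gene families, the test of the count alone under other scalings, the test of shared controls and the split count for lists were chosen after the results had been seen. The first rule for shared controls counted the observed covariance for that explanation. This rule was changed after the values were known. Among 27 families picked by symbol, with SF3B1 siRNA 8 of 10 tested Fanconi anaemia genes (FANC symbols) fell and 1 rose, with a median log2 fold change of -1.32, 14 of 22 nucleoporin genes (NUP symbols) fell and 2 rose (median -0.34), and 13 of 18 subunits of the vacuolar proton pump (ATP6V symbols) rose and 2 fell (median 0.42). Of long noncoding genes, 51 of 97 with LINC symbols fell and 14 rose (median -0.49) and 97 of 199 with antisense symbols fell and 22 rose (median -0.47); antisense genes commonly overlap a gene on the other strand, so their values are uncertain. These medians kept their sign under median-centred, quantile and plain read total scaling. Camera called these 5 (adjusted p = 0.00387, 0.00501, 0.0147, 0.00387 and 0.00148). It also called SNORA and SNORD genes, of which 23 of 35 rose and 0 fell (adjusted p = 0.00148), and none of the other families. The 5 described are thus among the families called, so these calls are no separate support. With an estimated correlation none was called (adjusted p = 0.764, 0.824, 0.77, 0.482 and 0.514 for the 5).

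Other lists fixed beforehand were not called by camera with SF3B1 siRNA, alternatives aside. Fry called those of histones, p53 targets, EMT and matrix genes and ductal markers (adjusted p = 0.000468, 0.000944, 0.000944 and 0.00393). It also called apoptosis regulators, HIF pathway components, intronless genes and ribosome biogenesis genes (0.00579, 0.0437, 0.0471 and 0.0471). The TCA, cholesterol, stress response and NF-kB lists were not called by fry (0.359, 0.308, 0.207 and 0.231). Of 23 p53 targets 10 rose and 4 fell (9 and 7 with plain read totals, 11 and 2 with median-centred libraries), with GADD45A at 1.44 (SE 0.078) and SESN1 at 1.32 (SE 0.097), and the list was not called by camera (adjusted p = 0.142; fry 0.000944). Of 35 TCA cycle and respiratory chain genes 14 rose and 11 fell, but 11 rose and 14 fell with quantile normalization and 9 and 16 with plain read totals, with UQCRC2 at -2.12 (SE 0.081) and OGDH at -1.38 (SE 0.074). Of 23 cholesterol genes 4 rose and 11 fell, with LSS at -1.59 (SE 0.182), and a camera adjusted p of 0.142 that was 0.039 without siCtrl_Hx replicate 5. Of 25 ribosome biogenesis genes 8 rose and 9 fell (9 and 6 with median-centred libraries, 6 and 11 with quantile normalization, 5 and 11 with plain read totals), with NPM1 at -1.32 (SE 0.075). Of 29 EMT and matrix genes 16 rose and 3 fell, or 18 and 5 with the block (camera adjusted p = 0.0517; 0.0291 with the block, and from 0.0341 to 0.0489 without siCtrl_Hx replicate 2, siCtrl_Hx replicate 8 or either siCtrl_Nx library), with CD44 at 0.95 (SE 0.088) and CCN2 at 1.52 (SE 0.165). Of 28 stress response genes 13 rose and 3 fell, or 16 and 5 with the block (0.142; 0.0495 with the block and 0.0251 without siCtrl_Hx replicate 8). Of 12 NF-kB genes 4 rose and 0 fell (0.307; 0.042 without siCtrl_Hx replicate 8), or 6 and 1 with the block, but only 2 rose with quantile normalization or plain read totals. Of the 4, ICAM1 and NFKB1 lost the call under both scalings and without siCtrl_Hx replicate 2 (adjusted p = 0.116 and 0.101), siCtrl_Hx replicate 5 (0.0764 and 0.113), siSF3B1_Hx replicate 6 (0.0758 and 0.054) or siSF3B1_Hx replicate 9 (0.116 and 0.122). Of 24 intronless genes 14 rose and 4 fell (0.134; 0.0383 without siSF3B1_Hx replicate 6), or 8 and 5 with plain read totals. Of 7 histone genes 3 rose and 0 fell (5 rose with quantile normalization), of 19 apoptosis regulators 10 rose and 3 fell, and of 11 ductal markers 7 rose and 1 fell, with KRT7 at -1.44 (SE 0.168) and KRT19 at 0.83 (SE 0.099). Of 11 HIF pathway components 6 rose and 3 fell. Adjusted over the list alone, 10 p53 targets rose and 3 fell, 2 NF-kB genes rose, 6 HIF pathway components rose and 4 fell, and the other lists named here had the same counts. By camera the real split of the hypoxic libraries called 10 lists and the highest other 11, with 4 of 10 splits at 10 or more, but each other split mixes the siRNAs 2 to 1 and keeps part of their difference, and 10 splits are too few for a share under 0.05. At least 1 of these mixed splits gave a list median larger in size than the real one for 7 lists: interferon (0.684 against 0.597, called in 4 of 9), mitosis (0.415 against -0.286, called in 6), stress response (0.401 against 0.291, called in 4), NF-kB (0.684 against 0.164, called in 4), p53 (0.205 against 0.107, called in 0), ribosome biogenesis (0.108 against -0.042, called in 1) and TCA cycle genes (0.051 against 0.022, called in 0). Mixed splits also called lists whose medians stayed smaller in size than the real one. Among these, DNA replication was called in 9 of 9 (up to 0.632 against -1.451) and canonical HIF targets in 6 (0.405 against -0.678). Glycolysis was called in 5 (0.247 against -0.269) and heat shock in 6 (0.28 against 0.589). Immediate early genes were called in 5 (0.492 against 0.591), as were SR and hnRNP factors (0.141 against 0.309).

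SF3B1 siRNA changed about 66% of tested genes. The real split of the 6 hypoxic libraries gave 8650 genes by limma and the highest of the other splits 0 (up to 368 at an unadjusted p under 0.05), over all 10 splits and over the 4 that part all 3 pairs of library numbers. Each other split mixes the siRNAs 2 to 1, which puts their difference into the spread within groups and lowers the count by design. The contrast of 8650 with 0 therefore decides little. Only 1 of 10 splits was as large, and 10 splits are too few for a share under 0.05. Other scalings moved the share of rises by up to 11.4 points, past the limit of 10 points set before that test. The balance of directions may therefore depend on scaling. They moved the count by at most 1.017 times, a test added after that result. A shift of scaling trades rises for falls, so the total can stay alike, and this ratio does not decide whether scaling contributes to the count. Taking a smooth trend on transcript GC content and length out of each library left 8831 genes, against 8552 before over the same 12920 genes, which argues against that trend. Exon number correlated with the fold change across 12051 protein-coding genes (Spearman rho -0.17, permutation p = 1e-04, the smallest that 10000 permutations can give). This met the rule set before that test, though genes are not independent. Medians did not fall steadily, with 0.25 for 1 exon, 0.06 for 2 to 3, 0.18 for 4 to 6, 0.12 for 7 to 12, -0.03 for 13 to 20 and -0.21 for over 20. A hypothesis that genes with many introns lose more mRNA when SF3B1 is low stays open.

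Small RNA genes inside host genes were higher with SF3B1 siRNA: 24 of 35 rose and 1 fell, with a median of 0.92 against 0.35 for their hosts. Reads from unspliced host transcripts could raise them, and the median difference from the hosts was 0.418 (95% bootstrap interval over 24 hosts -0.01 to 1.06), which does not decide; for the 28 snoRNA genes alone it was 0.442 (interval 0.225 to 1.137). For the 14 genes with a mean log2 CPM above 1, of which 10 rose and 1 fell with a median of 0.595, it was 0.353 (interval -0.107 to 1.498). This decides nothing on low read numbers, since the interval over all 35 includes 0 as well. The rule set before the test counted such an interval for low read numbers. It was changed after the values were known. For the 8 genes outside host exons, of which 6 rose and 1 fell while their hosts had a median of -0.12, the median difference was 1.285 (interval -0.059 to 1.792). The other small RNA genes overlap host exons, so their values are uncertain. No biological explanation was tested.

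The HIF lists fell with SF3B1 siRNA. The median of the 53 tested members of both lists was -0.468, below the 2.5th percentile (-0.02) and below the lowest (-0.219) of 10000 lists matched on mean expression and exon number, whose median was 0.158, which argues against those properties as the source. Chance values of the shared siCtrl hypoxia libraries stay open for the opposite changes over all genes: the covariance of -0.0489 lay inside the range of simulations that keep the gene-gene correlation, but below those with independent genes or with the library-number sets (lowest -0.0471), and with the controls split its mean was -0.0372, below the lowest simulated mean (-0.0221) though below the simulated range in only 2 of 6 splits. The list median of -0.468 lay below the simulated range of -0.227 to 0.232 with the correlation kept and of -0.156 to 0.156 with the sets, and with the controls split it was from -0.652 to -0.265, below 0 in each of the 6 splits, for which no range of list medians was simulated. An effect of SF3B1 siRNA on HIF target genes stays among the open explanations, and how it would act was not tested.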
